A study of Homo sapiens with 58 samples.

How the data were processed

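Colon biopsies from 53 people, with 1 expression array each, were compared in 4 groups taken from the labels: 11 healthy controls, 14 samples with colon-only Crohn's disease, 18 with ileocolonic Crohn's disease and 10 with ulcerative colitis. The 5 arrays of an internal control RNA stayed outside every test. Per the labels, the authors summarised the arrays with RMA (version not given). The deposited unit was a ratio on a linear scale, checked in the values: of 26121 probe sets 26116 had a mean over the healthy controls within 0.0001 of 1. The 5 internal control columns were the same to a relative difference of 2.44e-07, as they would be after division of each array batch by its own internal control, so they give no measure of technical spread. The deposited values ended at a floor of 0.01, reached by 145 of 1384413 values in 27 probe sets. The values hold no absolute level and no control probe sets, so no depth, background or RNA quality can be given per sample, and the number of arrays and the spread between them set the precision. The images and intensities of the arrays were not analysed here.

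Probe sets were joined to gene symbols through their RefSeq identifiers and a table of annotation names. Of the probe sets 20443 had 1 symbol, 0 had several and 5678 had none, and 39 probe sets of XIST, TSIX and Y-linked genes were left out. Each of the 15948 genes was represented by its probe set with the largest interquartile range over the 53 samples, which mattered for 2883 genes with several. Values were log2 transformed without a pseudocount.

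Limma 3.58.1 in R 4.3.3 fitted 1 linear model with a mean per group to all 53 samples, followed by empirical Bayes moderation, and the 6 differences between groups were tested with Benjamini-Hochberg adjustment at 0.05 over all genes. Intervals are 95% intervals. Gene lists were 39 fixed sets written before the data were examined, with 477 distinct genes of which 451 were measured, and some genes stand in more than 1 list. They were tested with limma's camera at a preset inter-gene correlation of 0.01 and, as alternatives, with the correlation estimated per list and with fry, each adjusted over the 39 lists. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of 1 list. A list score is the mean z-score of its members over the 53 samples. Relations between scores (6 tests) and spread of scores (9 tests) were tested with 100000 permutations and adjusted by Benjamini-Hochberg. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 did the remaining work.

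Genes named in the text followed a rule set before the data were examined. In each comparison with healthy controls these were the 8 largest rises and 8 largest falls among called genes, and between disease groups the 5 largest each way, or the 3 smallest p-values where none was called. In every comparison up to 3 members of each list with the smallest adjusted p, and TNFRSF6B and PSMG1, were added. Genes named in 1 comparison may be given in the others, and some genes picked by the rule are not reported here. XIST, TSIX, Y-linked genes and genes with common germline deletions or null alleles were passed over. Genes used to describe array clusters or colon position (such as CH25H, ARSL and the genes of a list of 15 position genes) were chosen after the data were seen.

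The series text says that the arrays were run in 5 batches, and the labels do not give the batch of a sample. A planned recovery of batches from spike-in probe sets could not be run, because the deposited values hold none. After the data were seen, the 53 arrays were instead grouped by average linkage on the correlation of 144 probe sets of 138 genes into 5 clusters named A to E. The genes were picked by the start of their symbol, from families such as olfactory receptors that are mostly not known to be made in colon. Expression in colon was not checked gene by gene. Ward linkage, and 391 probe sets with either linkage, gave the same 5 clusters (adjusted Rand index of 1). The clusters are not known to be the batches, but they followed the replicate numbers of the labels in runs. Healthy controls 1 to 3 lay in cluster A, 4 to 8 in B and 9 to 11 in C. Colon-only samples 1 to 5 lay in B, 6 to 10 in C, 11 in D and 12 to 14 in E. Ulcerative colitis sample 1 lay in A, 2 to 6 in E and 7 to 10 in C. Ileocolonic samples lay in more broken runs. Array batches could give such runs, and the labels do not give the order of processing. The clusters were used as a fixed term in an added model, and cluster C, which alone held all 4 groups, was also fitted alone.

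Replicate numbers in the labels do not pair the samples. Across groups 66 pairs of samples share a number, their correlations after removal of group means ran from -0.492 to 0.680 with a median of 0.0563, against -0.00694 for other pairs, and 30 of the 66 were over 0.1. A model with the number as a block was therefore run as an alternative only.

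Alternatives chosen before the data were examined were the mean of a gene's probe sets, every probe set, median centring, quantile normalization, leaving out the less variable genes, pseudocounts of 0.1 and 1, only the 2 groups compared, array weights, eBayes with trend and robust, a Wilcoxon rank-sum test, the replicate block, list scores as covariates, and stricter thresholds. Alternatives chosen afterwards were the array cluster, cluster C alone, the cluster with median centring, leaving out single arrays and a neutrophil score covariate. The tests and both models were tested on simulated data with the same group sizes and spread, where 3.28% to 7.41% of called genes were false and fry and camera called a shifted list and no other. The simulated genes varied independently, and cluster offsets were simulated only for the model with the cluster. The simulation therefore does not measure false calls among correlated genes or lists, or from offsets left out of the model. For every comparison 100 distinct splits of its samples, the real one included, were tested in the same way.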

Results

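RNA from colon biopsies of 53 people was hybridised to expression arrays, 1 array per person. The labels put 11 samples in a healthy control group, 14 in a group with Crohn's disease of the colon only, 18 in a group with ileocolonic Crohn's disease (disease of both the ileum and the colon) and 10 in a group with ulcerative colitis. Another 5 arrays held an internal control RNA, 1 per array batch, and were not compared with the groups. Biopsies came from the most proximal affected colon segment, some at diagnosis and some during therapy, and the labels do not say which sample is which. The deposited values were ratios, with each probe set's mean over the healthy controls set to 1, so the absolute level and the depth of each array are unknown and the number of arrays limits the precision. The median ratio of an array lay between 0.846 and 1.07. All changes below are differences of mean log2 ratios between groups, with standard errors (SE), over 15948 genes. P-values measure the spread between samples of the same label.

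The arrays fell into 5 clusters, A to E, when they were grouped by 138 genes. These were picked by the start of their symbol, from families mostly not known to be made in colon. Arrays correlated with a median r of 0.358 within a cluster and -0.125 between clusters over the 144 probe sets of these genes. The clusters were built on this correlation, so the difference does not test them. Clusters A and B held 8 of the 11 healthy controls, 5 of the 14 colon-only samples, 3 of the 18 ileocolonic samples and 1 of the 10 ulcerative colitis samples. The share of arrays in clusters C to E was 27.3% in healthy controls, 64.3% in colon-only Crohn's disease, 83.3% in ileocolonic Crohn's disease and 90.0% in ulcerative colitis. Healthy controls alone differed between these clusters. The difference between clusters C to E and clusters A and B correlated across genes with the same difference in colon-only samples (r = 0.847) and in ileocolonic samples (r = 0.831), although genes are not independent replicates. It was over 1 log2 unit with the same sign in all 4 groups for 275 genes and over 2 for 15, with 1 ulcerative colitis array in clusters A and B. Among the 15, CPA3, a mast cell protease (4.34 in healthy controls), CPVL (4.36), LYZ (3.01) and CCL2 (2.82) were higher in clusters C to E. Only OLFM4 (-4.44) and ARSL (-2.07) were lower. In the healthy, colon-only and ulcerative colitis groups each cluster held consecutive replicate numbers, as array batches could give. The cluster term may also take out differences in immune cell content, which was not tested. Every comparison is therefore given without and with the array cluster as a term of the model, an addition made after the data were seen.

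**Figure D1:**
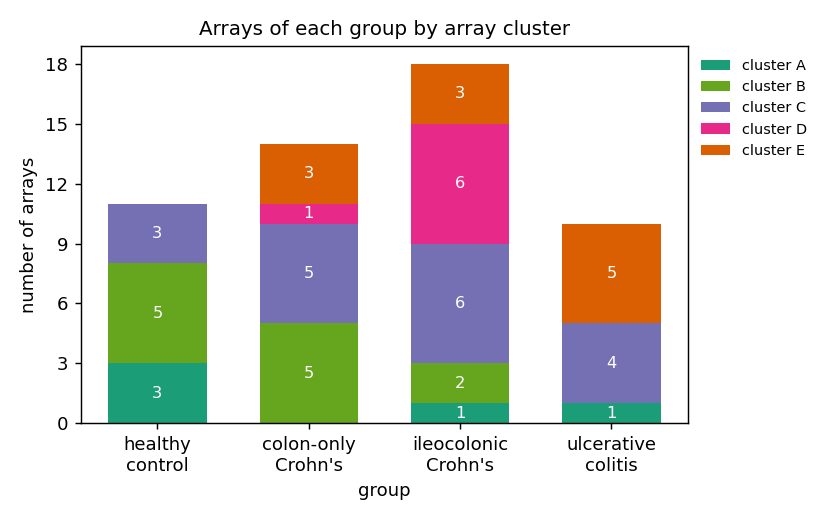
Stacked bars give the number of arrays (y axis) of each group (x axis) in array clusters A to E, with the count written in each segment. Healthy controls had 8 arrays in clusters A and B and 3 in cluster C, while 9 of the 10 ulcerative colitis arrays lay in clusters C and E.

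The comparison of ulcerative colitis with healthy controls asked how colon biopsies of this disease differ from healthy colon. The labels do not say how inflamed a sample was. SLC6A14, an amino acid transporter, rose by 6.11 (log2, SE 0.98, n = 10 against 11, adjusted p = 1.74e-05), a 69.1-fold rise, and lay above the healthy mean in 9 of 10 samples. DUOX2, an epithelial oxidase that makes hydrogen peroxide at the mucosal surface, rose by 5.65 (SE 0.78, adjusted p = 4.98e-06) and lay above the healthy mean in 10 of 10 samples. AQP8, a water channel of surface colonocytes, fell by 4.72 (SE 0.68, adjusted p = 9.05e-06) and lay below the healthy mean in 9 of 10 samples. With the cluster in the model these changes were 5.11 for SLC6A14 (adjusted p = 0.0031), 4.86 for DUOX2 (adjusted p = 0.00127) and -4.78 for AQP8 (adjusted p = 0.000616).

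**Figure D2:**
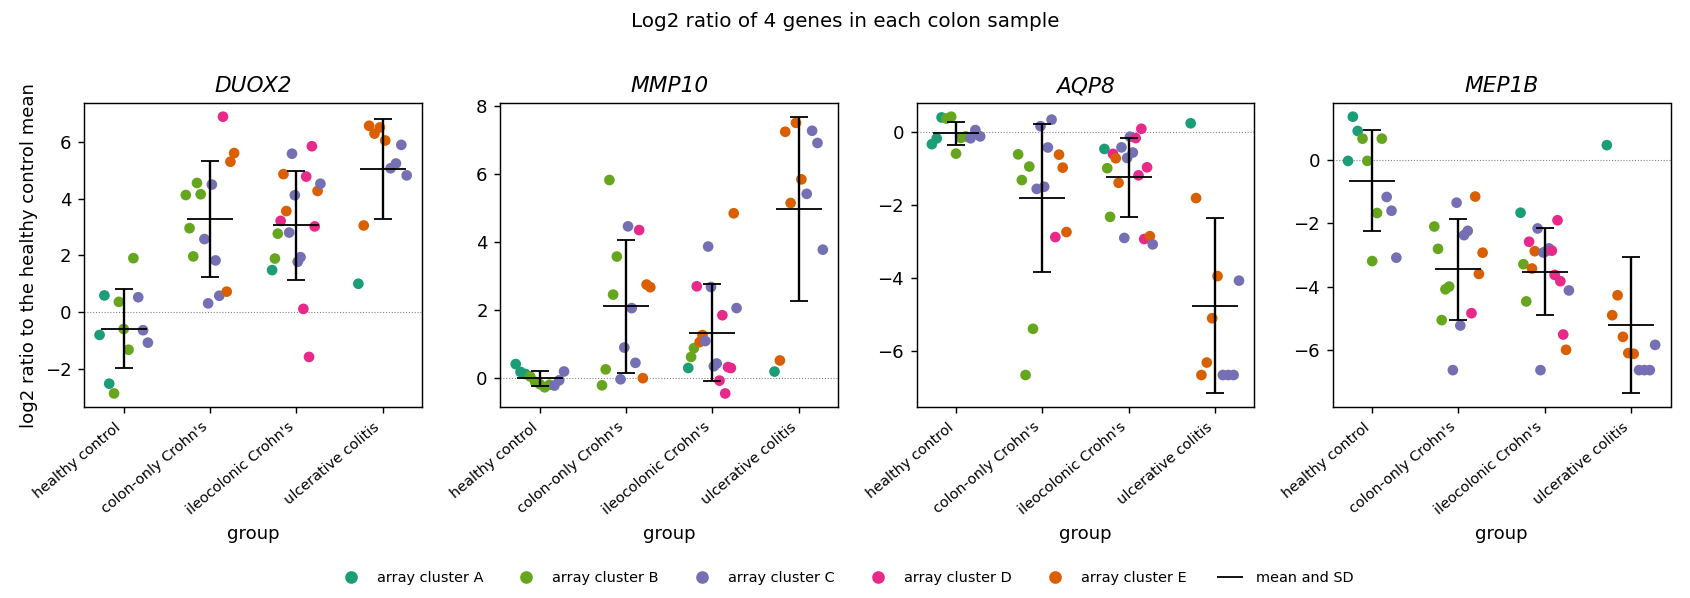
Each point is the log2 ratio to the healthy control mean (y axis) of DUOX2, MMP10, AQP8 or MEP1B in 1 sample, by group (x axis) and coloured by array cluster, and black bars give the group mean and SD. Mean DUOX2 was -0.59 in healthy controls and 5.06 in ulcerative colitis, and mean AQP8 was -0.03 and -4.75, with 4 of the 10 ulcerative colitis samples at the lowest deposited ratio.

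Inflammatory and matrix-remodelling genes rose together in ulcerative colitis. Of 10 measured CXCR2-ligand and myeloid chemokines, which draw neutrophils and monocytes into tissue, 9 rose and 1 did not pass, 6 of them rose with the cluster in the model, and examples are CXCL1 at 4.14 (SE 0.66; 3.64 with the cluster) and CXCL6 at 4.28 (SE 0.76; 3.48). Of 14 neutrophil markers 10 rose with and without the cluster, among them FCGR3B at 2.68 (SE 0.57) and S100A8 at 4.05 (SE 0.88). Of 11 genes in the metalloproteinase list, enzymes that cut extracellular matrix, 8 rose, including MMP3 at 5.45 (SE 0.91), MMP10 at 5.00 (SE 0.75) and MMP1 at 4.84 (SE 0.82), and 6 rose with the cluster. All 18 collagen and fibroblast matrix genes rose, among them COL6A3 at 2.50 (SE 0.38) and COL1A2 at 1.92 (SE 0.33), and 12 rose with the cluster. All 12 complement genes rose, among them C1R at 1.99 (SE 0.35) and C4BPB at 2.85 (SE 0.50). With the cluster 5 of the 12 rose, and their median change went from 1.91 to 0.89. Adjusted over the list alone, 9, 10, 9, 18 and 12 members of these 5 lists rose. The test fry, which asks whether a list's genes move on balance one way, gave adjusted p = 1.18e-05 for the chemokines, 0.00261 for the neutrophil markers, 6.18e-06 for the metalloproteinases, 1.05e-05 for the matrix genes and 1.15e-05 for complement. With the cluster these were 0.00129, 0.0111, 0.00129, 0.00484 and 0.0111. The test camera with a correlation estimated per list called none of these 5 lists and no other list in ulcerative colitis (smallest adjusted p = 0.181).

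Epithelial defence and secretory stress genes rose as well. Of 16 genes of the epithelial antimicrobial response 10 rose and 6 did not pass, 8 rose with the cluster in the model, and examples are DUOXA2, the maturation factor of DUOX2, at 3.73 (SE 0.59) and NOS2, the inducible nitric oxide synthase, at 2.54 (SE 0.46). Of 12 endoplasmic reticulum stress genes 11 rose, 10 with the cluster, including XBP1, a transcription factor of the unfolded protein response, at 1.39 (SE 0.21). Plasma cell genes rose in 8 of 9 cases, 7 with the cluster, including MZB1 at 2.21 (SE 0.32) and FKBP11 at 2.36 (SE 0.31). Interferon-gamma response genes rose in 10 of 13 cases and fell in 1, and 6 rose with the cluster, for example WARS1 at 1.61 (SE 0.33). Inflammatory cytokines rose in 8 of 14 cases, 5 with the cluster, including IL1B at 2.30 (SE 0.54). In the Th17 and IL-22 axis 6 of 10 genes rose and 2 fell, 2 rose and 0 fell with the cluster, and IL17A, the defining cytokine of Th17 cells, rose by 0.58 (SE 0.12; 0.56 with the cluster). Type I interferon genes went both ways, with 4 of 12 higher, 2 lower, 0 called with the cluster and a fry adjusted p of 0.531. Adjusted over the list alone the higher and lower counts were 11 and 1 for the antimicrobial genes and the same as above for the stress, plasma cell, interferon, cytokine and Th17 lists.

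The absorptive epithelium moved the other way. Of 21 absorptive colonocyte genes 17 fell and 4 did not pass, 15 fell with the cluster in the model, and adjusted over the list alone 18 fell. Examples are GUCA2A, which encodes the secreted peptide guanylin, at -3.41 (SE 0.56), and SLC26A2, a sulphate transporter, at -2.76 (SE 0.43). All 19 genes of fatty acid oxidation and ketogenesis fell, 18 of them with the cluster, among them ACADS, a short-chain acyl-CoA dehydrogenase, at -1.88 (SE 0.30). Of 16 genes of bile acid and xenobiotic handling 14 fell, 11 with the cluster, such as SULT1A2 at -2.02 (SE 0.30) and NR1I2, a xenobiotic-sensing nuclear receptor, at -1.36 (SE 0.25). Of 23 respiratory chain genes 21 fell by small amounts, with a list median of -0.41, and 12 fell with the cluster. Adjusted over the list alone 19 of the oxidation genes, 14 of the bile acid and xenobiotic genes and 22 of the respiratory chain genes fell. Fry adjusted p was 2.28e-05, 8.65e-06, 2.02e-05 and 0.000129 for these 4 lists, and 0.000537, 0.000403, 0.000403 and 0.0126 with the cluster. Markers common to all epithelial cells also fell in 7 of 11 cases, with a median of -0.80, and in 2 of 11 with the cluster. MEP1B, a brush border protease, fell by 4.59 (SE 0.70) and HSD3B2, an enzyme of steroid synthesis, by 4.40 (SE 0.93). PRAC1, a gene expressed in distal more than proximal colon, rose by 4.14 (SE 1.38, adjusted p = 0.0115; 2.47 and adjusted p = 0.19 with the cluster). Among healthy controls its mean was -3.23 (SD 3.29) in clusters A and B and -0.527 (SD 0.192) in cluster C. Healthy controls have no affected segment, and the labels do not give the colon segment of a sample. Segment and disease therefore cannot be told apart in these changes.

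In total 3003 genes were higher and 5274 lower in ulcerative colitis than in healthy controls (limma, adjusted p under 0.05), 51.9% of those tested, and 931 and 469 of them differed at least 2-fold. With the cluster in the model 3062 genes were called, 2665 of them among the 8277, and with cluster C alone 1897 were called. Quantile normalization gave 3517, 1724 of them higher and 1793 lower, and the pan-epithelial score as covariate 4957. The median change over all genes was -0.10, and with each array centred on its median, which moves that median to 0.01, the balance turned to 4039 higher and 3394 lower. This centring shifts every gene of an array alike, so it can turn a list median near 0. The lowest deposited ratio was reached by 4 of the 10 ulcerative colitis arrays for AQP8, 3 for MEP1B, 6 for HSD3B2 and 5 for SLC51A, a bile acid transporter subunit that fell by 3.95 (SE 0.94), so the deposited floor limits the size of these falls. Ulcerative colitis sample 1 lay apart from the other 9 in several of the genes and lists named here. It was the only array of its group in cluster A, beside 3 healthy controls. Otherwise the 2 groups met only in cluster C, with 4 ulcerative colitis and 3 healthy arrays. The model with the cluster was not fitted without sample 1, so how far this array moves the values with the cluster is unknown. Camera at a preset correlation called 28 of 39 lists and none with an estimated correlation.

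**Figure D3:**
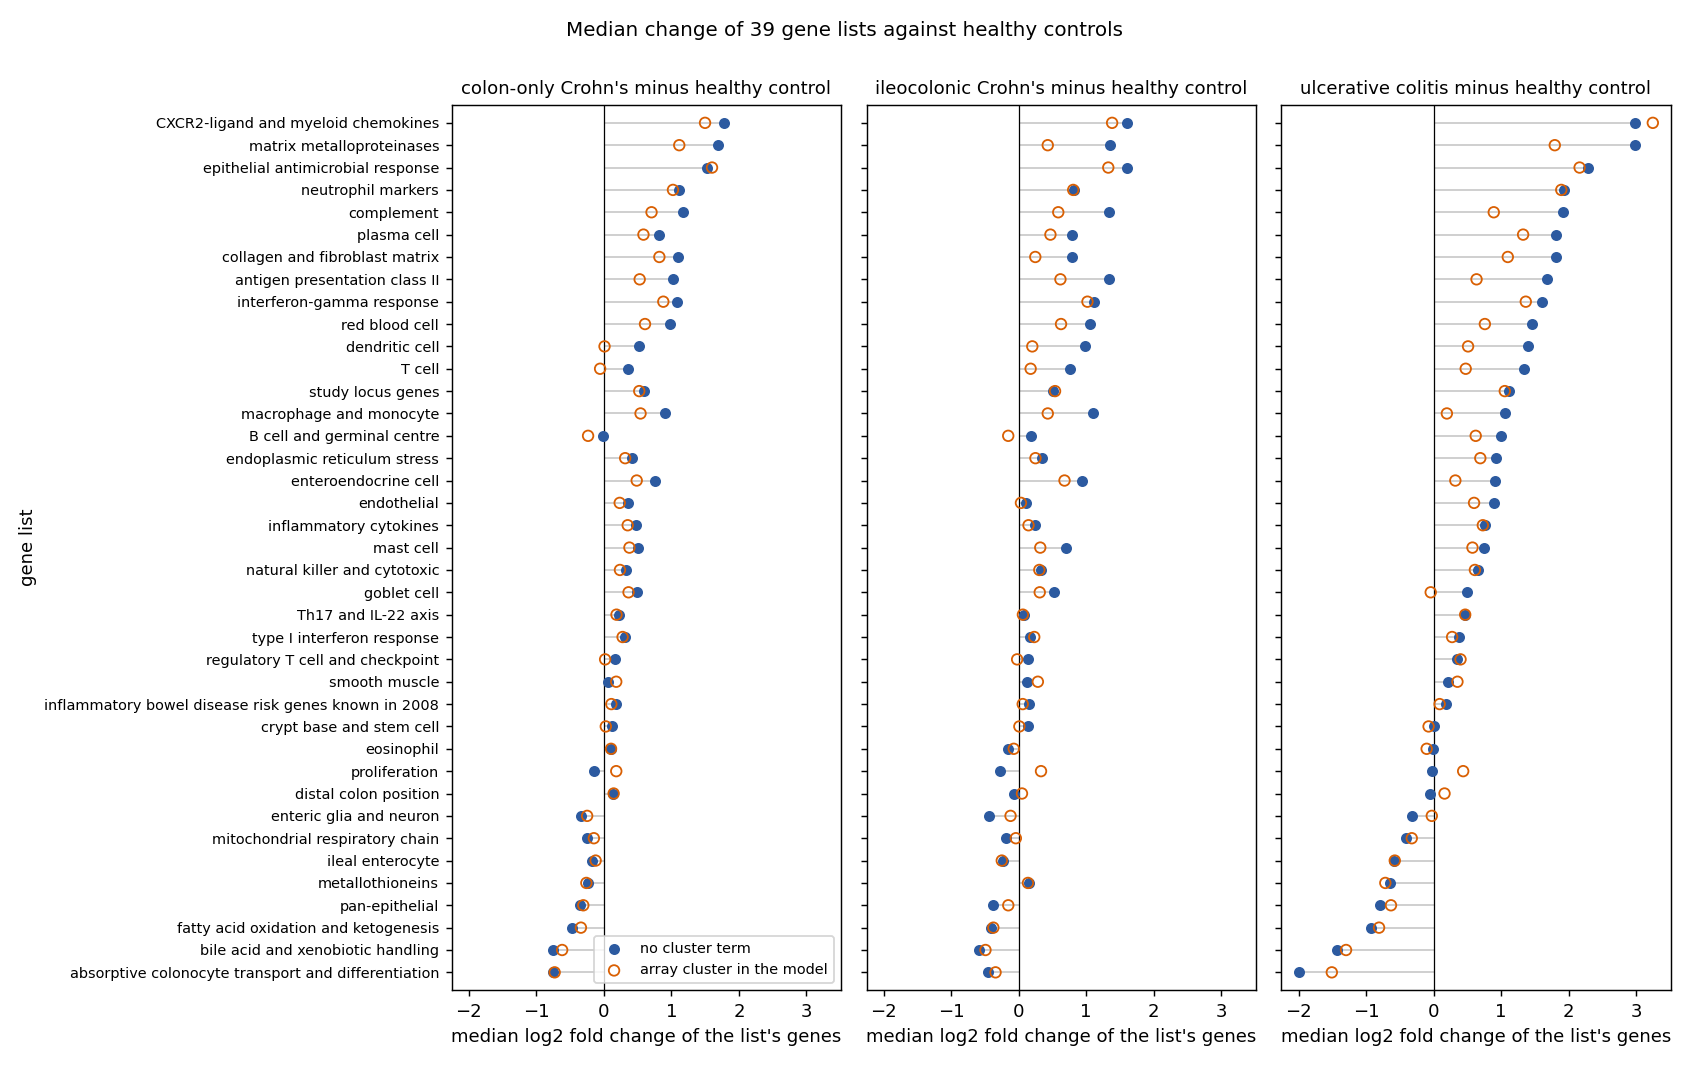
Points give the median log2 fold change (x axis) of the genes of each of 39 lists (y axis) in the 3 disease groups minus healthy controls, filled without and open with the array cluster in the model. In ulcerative colitis the chemokine list had a median of 2.98 and the absorptive colonocyte list -1.99, and with the cluster 3.25 and -1.51.

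Colon-only Crohn's disease was set against healthy controls to describe disease confined to the colon. DUOX2 rose by 3.89 (log2, SE 0.72, n = 14 against 11, adjusted p = 0.024), a 14.8-fold rise of the mean, and lay above the healthy mean in 14 of 14 samples. SLC6A14 rose by 3.77 (SE 0.91) and MMP3, a stromelysin, by 3.42 (SE 0.84), each above the healthy mean in 14 of 14 samples. SPINK4, a goblet cell peptide, rose by 2.32 (SE 0.57) and PCSK1, a prohormone convertase of endocrine cells, by 2.42 (SE 0.57). MEP1B fell by 2.81 (SE 0.65) in 14 of 14 samples, and HSD3B2 fell by 3.27 (SE 0.85) in 12 of 14 samples. None of these passed with the cluster in the model, where DUOX2 stood at 3.24 (adjusted p = 0.201), SLC6A14 at 2.95, MMP3 at 3.04, SPINK4 at 2.42, PCSK1 at 1.73, MEP1B at -2.01 and HSD3B2 at -2.35. PRAC1 stood at 2.81 (SE 1.27, adjusted p = 0.155), and at 1.21 with the cluster.

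Members of several lists were called in colon-only Crohn's disease without the cluster in the model, and with it no member was called over all genes tested. Of 18 collagen and fibroblast matrix genes 10 rose over all genes tested and 18 adjusted over the list alone, for example COL6A3 at 1.55 (SE 0.35). The interferon-gamma response had 6 of 13 genes higher, among them CXCL9, a chemokine for activated T cells, at 2.27 (SE 0.60), and 10 higher and 1 lower adjusted over the list alone. In the metalloproteinase and antimicrobial lists 4 of 11 and 4 of 16 genes rose, and 9 and 5 adjusted over the list alone. Chemokines rose in 3 of 10 cases, including CXCL1 at 2.50 (SE 0.61), and complement in 1 of 12, and adjusted over the list alone in 8 and 11. Plasma cell genes rose in 3 of 9 cases, including FKBP11 at 1.29 (SE 0.29), and in 8 adjusted over the list alone. Of 19 fatty acid oxidation genes 4 fell, including PPARA, a nuclear receptor that drives fatty acid oxidation, at -0.61 (SE 0.14), and 16 fell adjusted over the list alone. Absorptive colonocyte genes fell in 2 of 21 cases, SLC51B at -1.34 (SE 0.36) and SLC16A1, a butyrate transporter, at -1.32 (SE 0.36), and in 10 adjusted over the list alone. Counts adjusted over the list alone in the model with the cluster were 13 for matrix genes, 7 for the interferon-gamma response, 5 for metalloproteinases, 6 for antimicrobial genes, 9 for chemokines, 3 for complement, 7 for plasma cells, 3 for fatty acid oxidation and 0 for colonocyte genes. AQP8 did not pass (-1.75, SE 0.63, adjusted p = 0.0806). Fry adjusted p lay between 0.00546, for the chemokine, metalloproteinase, matrix and plasma cell lists, and 0.0273, for the colonocyte list, and between 0.0517 and 0.0815 for these lists with the cluster in the model. Camera with an estimated correlation called none of them.

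In colon-only Crohn's disease 282 genes were higher and 236 lower (limma), and 88 and 43 of them differed at least 2-fold. A pseudocount of 1 gave 267 higher and 442 lower, so the balance of directions turned with it. With the array cluster in the model no gene was called, and 2222 had an unadjusted p under 0.05, where other splits of the samples within clusters had a median of 1013 and 16 of 100 splits had as many. With the cluster all 518 genes kept their direction with a median change 0.722 of that without the cluster. Most of these calls also ended under other settings: 0 genes were called by eBayes with trend and robust, 1 with the pan-epithelial score as covariate, 7 by a Wilcoxon test and 11 with only the 2 groups compared, while array weights gave 1106 and the replicate block 843. Without healthy control arrays 5 and 6 together the count was 17, and without colon-only array 3, which had the lowest absorptive colonocyte score of its group (-3.44) and its highest neutrophil score (3.36), it was 167. Fry called 21 of 39 lists and none with the cluster in the model, and camera called 29 at the preset correlation and none with an estimated correlation (smallest adjusted p = 0.150 with an estimated correlation).

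Ileocolonic Crohn's disease was set against healthy controls to describe the colon when the ileum is also diseased. DUOX2 rose by 3.65 (log2, SE 0.68, n = 18 against 11, adjusted p = 0.00617) in 17 of 18 samples. CXCL9 rose by 3.32 (SE 0.57, adjusted p = 0.00247) and CXCL11 by 3.21 (SE 0.73), both chemokines for activated T cells and both higher in 18 of 18 samples. REG1B and REG1A, secreted lectins of the regenerating family, rose by 3.44 (SE 1.18) and 3.36 (SE 1.05). MEP1B fell by 2.89 (SE 0.61) in 18 of 18 samples, and GSTA1, a glutathione transferase, fell by 2.43 (SE 0.51) in 17 of 18. With the cluster in the model none passed, at 3.05 for DUOX2 (adjusted p = 0.308), 2.65 for CXCL9, 3.11 for CXCL11, 3.09 for REG1B, 2.93 for REG1A, -2.20 for MEP1B and -1.42 for GSTA1. PRAC1 stood at 2.97 (SE 1.21, adjusted p = 0.0639; 1.31 with the cluster). Other large changes shrank further: CPA3, a mast cell protease, rose by 2.82 (SE 0.71) without and stood at 1.07 with the cluster, and at 0.22 within cluster C, and CPVL, a carboxypeptidase-like protein, rose by 2.82 (SE 0.66) and stood at 1.04 and 0.03.

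Interferon-gamma response genes rose in 10 of 13 cases of ileocolonic Crohn's disease and fell in 1, with a median of 1.11 and, with the cluster, 1.02. Complement rose in 10 of 12 cases, for example C1R at 1.34 (SE 0.30), with a median of 1.34 and, with the cluster, 0.59. Antimicrobial genes rose in 8 of 16 cases and chemokines in 6 of 10, with medians of 1.60 and 1.60, and of 1.33 and 1.38 with the cluster. CCL2, a monocyte chemokine, rose by 2.39 (SE 0.52) and stood at 0.86 with the cluster. Collagen and fibroblast matrix genes rose in 10 of 18 cases, with a median that went from 0.78 to 0.25, and metalloproteinase list genes in 5 of 11, from 1.35 to 0.43. Fatty acid oxidation genes fell in 9 of 19 cases, including PPARA at -0.54 (SE 0.13), with medians of -0.42 and -0.38. Absorptive colonocyte genes fell in 1 of 21 cases, SLC16A1 at -0.91 (SE 0.34), with medians of -0.45 and -0.34, and AQP8 did not pass (-1.20, SE 0.60, adjusted p = 0.124). Adjusted over the list alone 10, 11, 12, 10, 13 and 5 genes of the 6 lists named before fatty acid oxidation rose, 1 fell in the interferon-gamma list and 1 in the metalloproteinase list, and 11 oxidation genes and 0 colonocyte genes fell. With the cluster these counts were 10 for the interferon-gamma response, 3 for antimicrobial genes, 0 for complement, chemokines, matrix and metalloproteinase genes, 1 for oxidation and 0 for colonocyte genes. Fry adjusted p was 0.00461 for the interferon-gamma list, 0.00138 for complement and 0.214 for the colonocyte list, and 0.0854, 0.191 and 0.4 with the cluster in the model, and camera with an estimated correlation called none of the lists.

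In ileocolonic Crohn's disease 1108 genes were higher and 2503 lower (limma), and 304 and 45 of them differed at least 2-fold. With the array cluster in the model none was called, and 1838 had an unadjusted p under 0.05, where other splits of the samples within clusters had a median of 669 and 11 of 100 splits had as many. Of the 3611 genes 98.5% kept their direction with the cluster, with a median change 0.436 of that without it, and 62.9% kept it within cluster C alone, where no gene was called. The replicate block gave 220 genes, the pan-epithelial score as covariate 1930 and a Wilcoxon test 2349. Without healthy control arrays 5 and 6 the count was 114, and with each array centred on its median it was 1491 higher and 963 lower. Fry called 23 of 39 lists and none with the cluster, and camera 25 at the preset correlation and none with an estimated correlation (smallest adjusted p = 0.156 with an estimated correlation).

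The 3 comparisons shared the same 11 healthy controls. Both Crohn's disease groups were higher in 234 genes and lower in 199, where independent calls would give 19.6 and 37.0. Colon-only Crohn's disease and ulcerative colitis shared 276 higher and 230 lower genes against 53.1 and 78.0, and ileocolonic Crohn's disease and ulcerative colitis 1035 and 2221 against 209 and 828. No gene was called in opposite directions. Across genes the fold changes of the 3 pairs correlated at r = 0.910, 0.929 and 0.896, and at 0.858, 0.870 and 0.773 with the cluster in the model. Simulated unchanged groups that shared 1 simulated control set gave 0.546, 0.532 and 0.520. These groups and controls were drawn at random from all 53 arrays after removal of group means. The simulation therefore lacks the imbalance of array clusters between healthy and disease groups, and its r may be too low a baseline. With the controls split into separate sets for the 2 comparisons the mean r over 20 draws was 0.719, 0.714 and 0.741, and the median numbers of shared higher and lower genes were 0 and 0, 0 and 0, and 245 and 610.5. The colon-only comparison then called a median of 0 genes beside the ileocolonic one and 1 beside ulcerative colitis, so the counts of 0 do not measure overlap. Both control sets came from the same healthy controls, most of them in clusters A and B. Offsets between array clusters can therefore remain in both fold changes and in their r.

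The colon-only and ileocolonic groups were compared with each other to ask whether the extent of Crohn's disease marks the colon. No gene passed (limma, smallest adjusted p = 0.674), with 1147 at an unadjusted p under 0.05, where other splits of these samples had a median of 515 and 20 of 100 splits had as many. The count was 0 with the cluster in the model (603 at an unadjusted p under 0.05), 1 by a Wilcoxon test and 77 with array weights, 76 of them higher in the colon-only group. The 3 smallest p-values belonged to TMEM121B (0.45, SE 0.10, higher in 13 of 14 samples), CCDC127 (0.30, SE 0.07) and HTR5A (0.24, SE 0.06), all of which missed the threshold. DUOX2 differed by 0.24 (95% interval -1.04 to 1.51) and AQP8 by -0.55 (95% interval -1.67 to 0.56). No member of any of the 39 lists was called over all genes tested, and fry called no list. Adjusted over the list alone 1 gene was called, IL5RA of the eosinophil list, a subunit of an interleukin receptor, at 0.26 (SE 0.07; 0.23 with the cluster, also called). The list medians ran from -0.48, for dendritic cells, to 0.29, for endothelial genes, with 0.26 for neutrophil markers, -0.41 for absorptive colonocyte genes and -0.44 for T cell genes. Camera at the preset correlation called 14 lists, as many as the median of other splits of these samples (14), and none with an estimated correlation (smallest adjusted p = 0.765 with an estimated correlation). In simulated data with the same group sizes the fit recovered 64.2% of genes changed by 0.5 log2 units and 98.5% of those changed by 1. These genes were picked at random and varied independently. The shares do not apply to genes with a wide spread such as DUOX2, whose interval included a change of 1.

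Colon-only Crohn's disease was then compared with ulcerative colitis, the usual diagnostic question for inflammation limited to the colon. AQP8 was higher in colon-only Crohn's disease by 2.97 (log2, SE 0.65, n = 14 against 10, adjusted p = 0.0392) in 12 of 14 samples, and by 3.30 with the cluster in the model (adjusted p = 0.0499). The size of this difference is limited by the deposited floor, reached by 4 of the 10 ulcerative colitis arrays and 1 colon-only array for AQP8. PCK1, an enzyme of gluconeogenesis, was higher by 2.77 (SE 0.70), GUCA2A by 2.12 (SE 0.53) and TRHDE, a peptidase that inactivates thyrotropin-releasing hormone, by 1.81 (SE 0.46). MMP10 was lower by log2 -2.88 (SE 0.71) in 13 of 14 samples, CDH3, which encodes P-cadherin, by -1.58 (SE 0.39), SERPINB4, a protease inhibitor, by -1.46 (SE 0.36) and ME1, malic enzyme, by -1.34 (SE 0.33). With the cluster TRHDE passed (2.16, adjusted p = 0.0499), and PCK1 (2.69), GUCA2A (2.14), MMP10 (-2.81), CDH3 (-1.43), SERPINB4 (-1.55) and ME1 (-0.79) did not.

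By list, 5 of 21 absorptive colonocyte genes were higher in colon-only Crohn's disease than in ulcerative colitis, 9 adjusted over the list alone, with a fry adjusted p of 0.045, and 0.0616 with the cluster. Endoplasmic reticulum stress genes were lower in 2 of 12 cases, DNAJC3 at -0.99 (SE 0.24) and SEL1L at -0.56 (SE 0.14), and in 9 adjusted over the list alone (fry adjusted p = 0.0149, and 0.042 with the cluster). Fatty acid oxidation genes were higher in 0 of 19 cases and in 14 adjusted over the list alone (fry adjusted p = 0.0435, and 0.042 with the cluster). TIGIT, an inhibitory receptor of T cells, was lower by -1.07 (SE 0.26), the 1 called gene of 10 in the regulatory T cell and checkpoint list. Plasma cell genes were lower in 0 of 9 cases and in 6 adjusted over the list alone (fry adjusted p = 0.031, and 0.123 with the cluster). With the cluster the counts adjusted over the list alone were 7 for colonocyte, 8 for stress, 14 for oxidation and 3 for plasma cell genes. Over all genes tested, only 5 of the 120 genes called in this comparison were called again with the cluster, so most single calls ended.

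Between colon-only Crohn's disease and ulcerative colitis 67 genes were higher and 53 lower (limma), and 8 and 12 of them differed at least 2-fold. With the cluster in the model 8 were called, 5 of them among the 120, and 1713 were called within cluster C alone. Single arrays moved the count: 2788 genes were called without ulcerative colitis array 1 and 1575 without colon-only array 3, and no gene was called after quantile normalization, by a Wilcoxon test or with only the 2 groups compared, while array weights gave 5567. With each array centred on its median 31 were higher and 66 lower, so the balance of directions turned with the scaling. Fry called 7 of 39 lists and 4 with the cluster, and camera 24 at the preset correlation and none with an estimated correlation (smallest adjusted p = 0.332 with an estimated correlation).

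Ileocolonic Crohn's disease was compared with ulcerative colitis in the same way. AQP8 was higher in ileocolonic Crohn's disease by 3.52 (log2, SE 0.62, n = 18 against 10, adjusted p = 0.0013) in 18 of 18 samples, a size limited by the floor in 4 of the 10 ulcerative colitis arrays. PCK1 was higher by 3.39 (SE 0.66) and GUCA2A by 2.69 (SE 0.50). MMP10 was lower by log2 -3.65 (SE 0.67, adjusted p = 0.00206) in 18 of 18 samples, MMP1, a collagenase, by -3.41 (SE 0.74), MMP3 by -3.18 (SE 0.82) and SLC6A14 by -3.32 (SE 0.89). With the cluster in the model these stood at 3.61 for AQP8 (adjusted p = 0.00713), 3.25 for PCK1, 2.89 for GUCA2A, -3.48 for MMP10 (adjusted p = 0.0134), -2.95 for MMP1 and -3.04 for MMP3, all of which passed, and -3.12 for SLC6A14, which did not (adjusted p = 0.0531). IL17A was lower by -0.55 (SE 0.11, adjusted p = 0.00294), and -0.55 with the cluster.

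Absorptive colonocyte genes were higher in ileocolonic Crohn's disease than in ulcerative colitis in 10 of 21 cases, 18 adjusted over the list alone, and 7 with the cluster in the model. Fatty acid oxidation genes were higher in 6 of 19 cases, 16 adjusted over the list alone, and 6 with the cluster. Collagen and fibroblast matrix genes were lower in 7 of 18 cases, 13 adjusted over the list alone, including COL4A1 at -1.25 (SE 0.28) and COL12A1 at -1.55 (SE 0.36), and metalloproteinase list genes in 5 of 11, 7 adjusted over the list alone. Endothelial genes were lower in 5 of 13 cases, 8 adjusted over the list alone, including KDR, the main receptor of vascular endothelial growth factor, at -0.84 (SE 0.22), and endoplasmic reticulum stress genes in 4 of 12, 11 adjusted over the list alone. Metallothioneins, small metal-binding proteins, were higher in 4 of 7 cases, 7 adjusted over the list alone, including MT1M at 2.04 (SE 0.55). Plasma cell genes were lower in 3 of 9 cases, 6 adjusted over the list alone, including MZB1 at -1.47 (SE 0.29). With the cluster the counts adjusted over the list alone were 18, 16, 13, 5, 10, 11, 7 and 5 for these 8 lists in the order given. Fry adjusted p for these 8 lists lay between 0.00205, for the stress genes, and 0.0133, for the metallothioneins, and with the cluster between 0.00966 and 0.0206. Neutrophil markers were lower in 2 of 14 cases, 8 adjusted over the list alone and 0 with the cluster either way (median -1.16, fry adjusted p = 0.0646). The pan-epithelial list had no called member of 11, and 6 higher and 1 lower adjusted over the list alone (median 0.47, fry adjusted p = 0.224).

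Between ileocolonic Crohn's disease and ulcerative colitis 448 genes were higher and 486 lower (limma), and 94 and 103 of them differed at least 2-fold. The balance of directions moved with the setting. A pseudocount of 1 gave 282 higher and 644 lower, and cluster C alone 812 higher and 385 lower. With the cluster in the model 622 were called, 492 of them among the 934, and within cluster C alone 1197. The count was 2489 without ulcerative colitis array 1, 25 after quantile normalization, 26 with the neutrophil score in the model, 1666 by a Wilcoxon test and 5165 with array weights. Camera called 22 of 39 lists at the preset correlation and none with an estimated correlation (smallest adjusted p = 0.209 with an estimated correlation), and fry 12 with and without the cluster.

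The 2 genes that the study itself singled out at disease loci were TNFRSF6B, a decoy receptor for ligands of the tumour necrosis factor family, and PSMG1, a chaperone of proteasome assembly, so their direction here is not independent evidence. TNFRSF6B rose by 1.62 in ulcerative colitis (log2, SE 0.39, adjusted p = 0.000869; 1.57 and adjusted p = 0.0123 with the cluster) in 8 of 10 samples. It did not pass in colon-only Crohn's disease (0.77, SE 0.36, adjusted p = 0.164) or ileocolonic Crohn's disease (0.48, SE 0.34, adjusted p = 0.284), and it was lower in the ileocolonic group than in ulcerative colitis by log2 -1.14 (SE 0.35, adjusted p = 0.0411; -1.07 and adjusted p = 0.0823 with the cluster). PSMG1 rose by 0.60 in ulcerative colitis (SE 0.18, adjusted p = 0.0043; 0.54 and adjusted p = 0.045 with the cluster) and by 0.55 in ileocolonic Crohn's disease (SE 0.15, adjusted p = 0.0144; 0.58 and adjusted p = 0.308 with the cluster). In colon-only Crohn's disease it stood at 0.41 (SE 0.16, adjusted p = 0.11). Of 23 measured genes at inflammatory bowel disease loci known at the time of the study, 11 rose and 5 fell in ulcerative colitis, 12 and 6 adjusted over the list alone, with 4 and 1 called with the cluster. NOD2, an intracellular sensor of bacterial peptides, rose by 1.75 in ulcerative colitis (SE 0.31, adjusted p = 4.70e-05; 1.29 with the cluster), and SLC22A5, a carnitine transporter, fell by 1.88 (SE 0.33; -2.01 with the cluster). In colon-only and ileocolonic Crohn's disease 4 and 6 of the 23 rose, among them NOD2 at 1.08 (SE 0.29; 0.78 with the cluster) and 1.25 (SE 0.27; 0.79).

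Within each disease group, samples with higher neutrophil scores had lower absorptive colonocyte scores, a score being the mean over a list of gene z-scores. In colon-only Crohn's disease Pearson's r was -0.934 (n = 14, permutation p = 0.00026, adjusted p = 0.00078 over 6 relations) and Spearman's rho -0.789 (permutation p = 0.00124, adjusted p = 0.00744). In ileocolonic Crohn's disease r was -0.850 (n = 18, permutation p = 4e-05, adjusted p = 0.00024) and rho -0.657 (permutation p = 0.00385, adjusted p = 0.0115), and in ulcerative colitis r was -0.772 (n = 10, permutation p = 0.00912, adjusted p = 0.0182) and rho -0.733 (permutation p = 0.0202, adjusted p = 0.0405). Without the 2 samples farthest from the median neutrophil score r was -0.794, -0.723 and -0.517, and with each cluster's mean taken out it was -0.942, -0.907 and -0.640. Ileocolonic samples of clusters C and D alone, 6 in each, gave r of -0.885 and -0.968, and no other cluster held 6 samples of a disease group. Colon-only array 3, with the highest neutrophil score of its group (3.36), also had its lowest pan-epithelial score (-4.58). Whether the relation follows the overall epithelial content of the samples was not tested. The relation of antimicrobial to respiratory chain scores did not pass by Pearson's r in any group, at 0.0846, -0.344 and -0.531 (permutation p = 0.778, 0.161 and 0.115, adjusted p = 0.778, 0.193 and 0.172). With each cluster's mean taken out r was 0.293, -0.552 and -0.324. Ileocolonic samples of clusters C and D alone gave -0.773 and -0.451. These values with clusters were not tested. Spearman's rho passed in ileocolonic Crohn's disease (-0.517, permutation p = 0.0294, adjusted p = 0.0441) and not in the colon-only (0.0637) or ulcerative colitis group (-0.248).

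**Figure D4:**
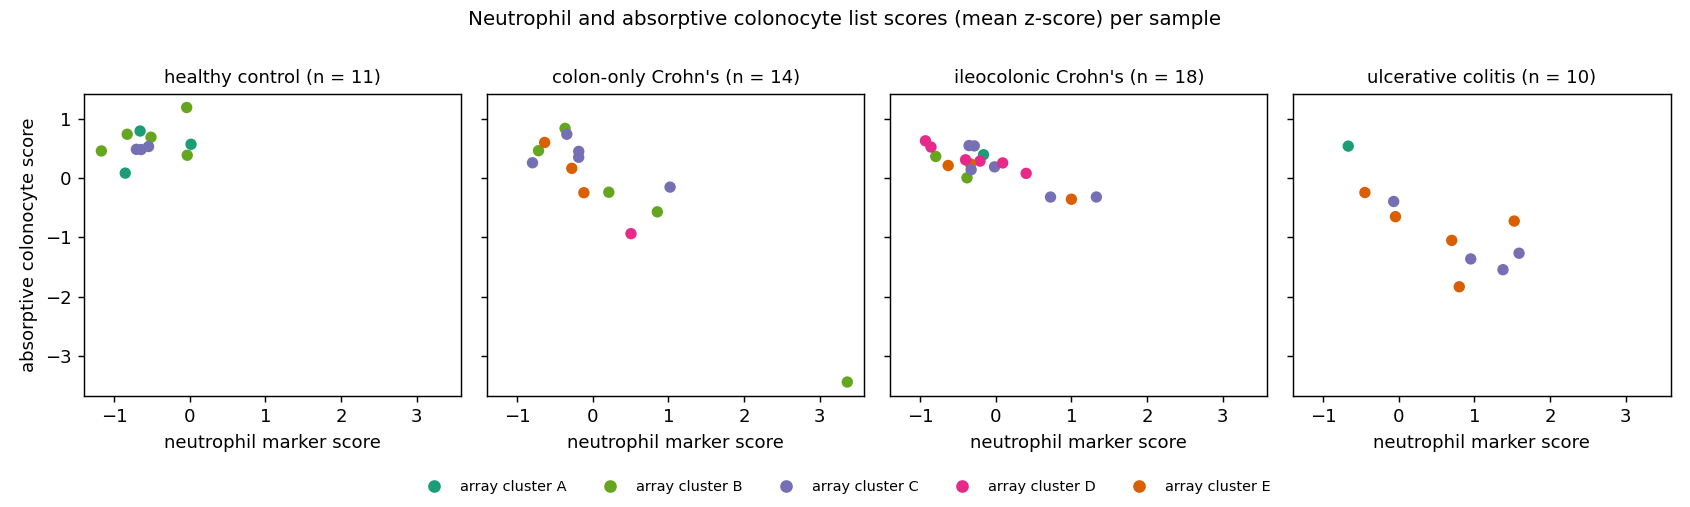
Each point is 1 sample, with its neutrophil marker score (x axis) and absorptive colonocyte score (y axis), both mean z-scores, in 1 panel per group and coloured by array cluster. Scores fell along the panel in colon-only Crohn's disease (r = -0.934), ileocolonic Crohn's disease (r = -0.850) and ulcerative colitis (r = -0.772).

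Some samples were taken at diagnosis and others during therapy, which raises the question of whether disease samples were more unlike each other than healthy ones. The mean absolute deviation from the group median was compared with that of healthy controls for 3 list scores in 3 groups. None of the 9 permutation tests passed after adjustment. The nearest were the absorptive colonocyte score in ulcerative colitis, with a deviation of 0.559 against 0.190 (permutation p = 0.00757, adjusted p = 0.0681), and the neutrophil score in ulcerative colitis, with 0.677 against 0.281 (permutation p = 0.0231, adjusted p = 0.104).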

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

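The genes called between ileocolonic Crohn's disease and ulcerative colitis with the cluster in the model, the precision of the model with clusters and the colon position score were tested only after the result was seen.

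Ulcerative colitis sample 1, an array of cluster A, lay far from the other 9 of its group in 8 of 59 items tested, 39 list scores and 20 named genes, by the gap to its nearest neighbour over the range of the group. Chance flags about 1 in 20 groups, here 2.95 items, and the items are correlated. Its list scores were low for complement (-0.905), endoplasmic reticulum stress (-0.522), T cells (-0.886), plasma cells (-0.864) and dendritic cells (-0.770), where the other 9 ran from 0.142, 0.465, 0.300, 0.516 and 0.222 upward. It was high in 3 genes that fell in the group, with log2 ratios of -0.41 for HSD3B2, 0.48 for MEP1B and 0.42 for TRHDE, where the others reached at most -3.55, -4.27 and -2.35.

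With the healthy-control difference between clusters taken out of sample 1, 0 of the 5 list scores stayed apart, but in 4 of them sample 1 stayed the lowest of its group (gap of 0.386 of the range for endoplasmic reticulum stress and 0.312 for plasma cells), so offsets between array clusters may explain part of its distance. Of the 3 genes 2 stayed apart (MEP1B and TRHDE) and HSD3B2 came back toward the others, so for the single genes the offsets cannot be told apart from other sources, with 3 healthy controls in cluster C to measure them. A healthy sample under an ulcerative colitis label stayed open: over the 1897 genes called within cluster C, the deviation of sample 1 from the healthy controls of cluster A correlated with the ulcerative colitis change at r = -0.181, inside the range of those 3 controls (-0.624 to 0.453), while the ileocolonic array of cluster A reached 0.476. A more proximal colon segment could not be told apart either, because the score of 8 proximal minus 7 distal genes was 0.549 with the offset out, above the other 9 (-1.87 to 0.329) by a gap of 0.0912 of the range, below the critical value for 10 samples. A biopsy with milder inflammation, at diagnosis or during therapy, was not tested, since the labels do not give the state of a sample.

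No gene of either Crohn's disease group was called against healthy controls with the array cluster in the model. Offsets between array clusters had what this needs: 96.2% of the genes called in ileocolonic and 90.9% of those called in colon-only Crohn's disease had a healthy-control difference, cluster C minus clusters A and B, of the same sign as the disease change. Of the 165 ways to pick 3 healthy controls, 1 and 4 gave as high a share (highest of the others 95.8% and 95.4%). The median offset times the difference in cluster shares was 0.23 for ileocolonic genes, with a median change of 0.37, and 0.18 for colon-only genes, with one of 0.66. Clusters D and E held no healthy controls, so their offsets were not measured. The product therefore cannot bound how much of the change the clusters account for. The calls also rested on healthy control arrays 5 and 6, both of cluster B. Their log2 ratios had the widest interquartile ranges of the controls (0.705 and 0.606). Without these 2 arrays, and so with fewer controls, 114 ileocolonic and 17 colon-only genes were called in the model without the cluster. The offsets were not measured again without them. A loss of precision is argued against for the median called gene, since the standard error with the cluster had a median of 0.951 and 0.968 of that without it. The median fold change of the called genes went from 0.37 to 0.16 (SE 0.112 to 0.103) and from 0.66 to 0.48 (SE 0.177 to 0.164). For 1315 of the 3611 ileocolonic and 188 of the 518 colon-only genes the standard error rose with the cluster. In those genes a loss of precision stays open. A disease difference inside clusters cannot be told apart from chance in these gene counts: 11 and 16 of 100 splits within clusters had as many genes at an unadjusted p under 0.05 as the real 1838 and 2222, with 4260 and 5216 the highest of the others. It stays open, since camera at the preset correlation called 24 lists in ileocolonic Crohn's disease, as many as 2 of 100 splits within clusters, while fry with the cluster called 0.

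Ileocolonic Crohn's disease and ulcerative colitis differed in 934 genes, and 3 explanations were tested by a term in the model. Offsets between array clusters as the whole source are argued against, because the fold changes kept a median ratio of 0.939 with the cluster and 492 genes stayed called (median fold 0.61 to 0.59, SE 0.170 to 0.172). Less epithelium in the ulcerative colitis biopsies left a ratio of 0.787 and 412 genes (fold to 0.48, SE to 0.142), and more neutrophil inflammation a ratio of 0.702 and 26 genes (fold to 0.43, SE to 0.155). The mean pan-epithelial score was 0.0647 in the ileocolonic group and -0.429 in ulcerative colitis, and the mean neutrophil score -0.117 and 0.572. With the neutrophil score most calls ended because the folds shrank, so inflammation may account for part of the difference, and the diseases themselves stay open as the remainder.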

How the results depend on the processing

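All models with the array cluster, with single arrays left out or with the neutrophil score were chosen after the data were seen. The arrays give no signal over background, so what low signal limits cannot be said. Alternatives that need absolute level (the probe set with the highest mean, a filter on the lowest level) or control probe sets (batches from spike-ins, RNA quality) were not run. The cause of the movements given here was not tested, except where fewer samples, fewer genes, a stricter threshold or another unit made the count.

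The comparisons are ordered as colon-only Crohn's disease, ileocolonic Crohn's disease and ulcerative colitis against healthy controls, then colon-only against ileocolonic, colon-only against ulcerative colitis and ileocolonic against ulcerative colitis, with 518, 3611, 8277, 0, 120 and 934 genes called. Only counts that moved by over 1.5 times are given. With the less variable genes left out, the colon-only, ileocolonic and ulcerative colitis counts against healthy controls were 1016, 2273 and 5072, and colon-only against ulcerative colitis 253. With only the 2 groups compared, 11 genes were called for colon-only against healthy, 0 for colon-only against ulcerative colitis and 2175 for ileocolonic against ulcerative colitis. Array weights gave 1106 for colon-only against healthy, 77 between the Crohn's disease groups, 5567 for colon-only against ulcerative colitis and 5165 for ileocolonic against ulcerative colitis. EBayes with trend and robust gave 0 for colon-only against healthy. The Wilcoxon test gave 7 and 2349 for the Crohn's disease groups against healthy, 1 between them, and 0 and 1666 against ulcerative colitis. Quantile normalization gave 3517 for ulcerative colitis against healthy and 0 and 25 for the Crohn's disease groups against ulcerative colitis, and a pseudocount of 1 gave 237 for colon-only against ulcerative colitis.

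The replicate block gave 843 and 220 for the Crohn's disease groups against healthy and 1670 and 1945 against ulcerative colitis. The pan-epithelial score as covariate gave 1, 1930 and 4957 against healthy and 405 and 430 for the Crohn's disease groups against ulcerative colitis, and with the smooth muscle score as well the values were 1 for colon-only and 5131 for ulcerative colitis against healthy, and 437 and 410. The array cluster in the model gave 0, 0 and 3062 against healthy, and 8 and 622 against ulcerative colitis. Cluster C alone gave 0, 0 and 1897 against healthy and 1713 for colon-only against ulcerative colitis, and the cluster with median centring 0, 1 and 2752 against healthy and 3 for colon-only against ulcerative colitis. Without colon-only array 3 the counts were 167 against healthy and 1575 against ulcerative colitis, without healthy arrays 5 and 6 they were 17 and 114 for the Crohn's disease groups, and without ulcerative colitis array 1 they were 2788 and 2489. The neutrophil score gave 8 and 26 for the Crohn's disease groups against ulcerative colitis.

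Counted as probe sets, 855, 5913 and 13391 differed from healthy and 198 between colon-only Crohn's disease and ulcerative colitis. At least 2-fold, the counts were 131, 349 and 1400 against healthy and 20 and 197 against ulcerative colitis, and at an adjusted p under 0.01 they were 0 and 390 for the Crohn's disease groups against healthy and 0 and 131 against ulcerative colitis. Camera with an estimated correlation called 0 lists in all 6 comparisons. Fry called 0 lists between the Crohn's disease groups and 7 and 12 against ulcerative colitis, and with the cluster 0 and 0 for the Crohn's disease groups against healthy, 0 between them and 4 and 12 against ulcerative colitis.

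Of 735 results for single named genes, 521 kept their side of the threshold with the cluster in the model, 213 no longer passed, 1 came to pass and 0 reversed, and with each array centred on its median 713 kept their side. A result counts as reversed only where its sign turned and it was called without the setting, with it or both. Changes of sign in results called in neither fit stand among those that kept their side. Within cluster C alone 17 reversed in this sense, each with a value near 0 there (adjusted p from 0.861 to 0.998). In ileocolonic Crohn's disease against healthy controls these were GGTLC2 (0.16), CCR6 (-0.0535), LYZ (-0.11), NDUFS3 (0.00265), SMOC2 (-0.0236), HERPUD1 (-0.00588), DNAJB9 (-0.13), ICOS (-0.11), GZMK (-0.0155), PAX5 (0.0417), TNFRSF17 (-0.0784), CLEC10A (-0.0113), KIT (-0.0866), SIGLEC8 (0.0404), EGFL7 (0.0993) and SOX10 (0.0107), and in ulcerative colitis CD163 (-0.11). GFAP in ulcerative colitis turned to 0.0349 with the cluster and median centring.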

Other observations

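The splits of the samples for gene counts and all values with the array cluster were chosen only after the result was seen. In the lymphoid lists, ulcerative colitis differed from healthy controls mostly without the array cluster in the model. The values with the cluster rest in part on ulcerative colitis sample 1, the only array of its group in cluster A, whose T cell score was low (-0.886). T cell genes rose in 9 of 12 cases (median 1.33, fry adjusted p = 0.00119), for example CD3D, a chain of the T cell receptor complex, at 1.44 (SE 0.35), and with the cluster in 0 cases (median 0.48, fry adjusted p = 0.213). In ileocolonic Crohn's disease 5 T cell genes rose, 0 with the cluster (median 0.76 and 0.18), and 0 did in colon-only Crohn's disease, but no difference between the 2 groups passed for this list (fry adjusted p = 0.828). Regulatory T cell and checkpoint genes rose in 5 and fell in 2 of 10 cases in ulcerative colitis, with ICOS, a costimulatory receptor, at 1.96 (SE 0.40; 1.04 with the cluster). Natural killer and cytotoxic genes rose in 8 and fell in 1 of 11 cases, 3 with the cluster, with NKG7, a protein of cytotoxic granules, at 1.14 (SE 0.25; 0.87). B cell and germinal centre genes rose in 5 and fell in 1 of 13 cases, 1 with the cluster, with CD79A, part of the B cell receptor, at 1.25 (SE 0.27; 0.83). Adjusted over the list alone the higher and lower counts of these 4 lists were 10 and 0, 6 and 3, 8 and 1, and 5 and 1.

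Macrophage and monocyte genes rose in 4 of 8 cases in ulcerative colitis and 5 in ileocolonic Crohn's disease, and in 0 with the cluster in either, where their medians went from 1.06 to 0.20 and from 1.11 to 0.43. Dendritic cell genes rose in 9 of 10 cases in ulcerative colitis, 3 with the cluster, among them CCL22, a chemokine for regulatory T cells, at 0.99 (SE 0.24; 0.80). Mast cell genes rose in 4 and fell in 1 of 8 cases, 3 with the cluster, and HDC, the enzyme that makes histamine, rose by 1.13 (SE 0.21; 0.74). Eosinophil genes rose in 0 of 6 cases and fell in 2, with ALOX15 at -0.42 (SE 0.10; -0.27). Class II antigen presentation genes rose in 3 of 4 cases, 1 with the cluster, CD74 at 1.67 (SE 0.33; 0.74). Red blood cell genes rose in 4 and fell in 1 of 6 cases, 1 with the cluster, with HBB at 3.01 (SE 0.65; 1.35), and in 3 of 6 in each Crohn's disease group.

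Stromal, neural and epithelial lists went in both directions in ulcerative colitis. Endothelial genes rose in 9 and fell in 1 of 13 cases (fry adjusted p = 0.000908), 7 with the cluster (fry adjusted p = 0.0159), among them PECAM1 at 1.57 (SE 0.28; 1.05) and SELP, an adhesion receptor for leukocytes, at 1.51 (SE 0.34; 1.36). Smooth muscle genes rose in 2 of 10 cases with and without the cluster, with TAGLN at 1.19 (SE 0.29; 1.24). Enteric glia and neuron genes fell in 5 of 10 cases, 1 with the cluster. Goblet cell genes went both ways, with 4 higher and 2 lower of 12, SPINK4 at 3.07 (SE 0.62; 3.19) and ZG16, a mucus lectin, at -1.63 (SE 0.48; -1.57), and their median turned from 0.49 to -0.04 with the cluster. Enteroendocrine genes rose in 3 of 11 cases, 1 with the cluster, PCSK1 at 3.37 (SE 0.62; 2.10). Metallothioneins fell in 3 of 7 cases, 2 with the cluster, and ileal enterocyte genes in 5 of 8, 4 with the cluster, ALPI, an alkaline phosphatase of the brush border, at -0.94 (SE 0.17; -0.56). Distal colon position genes had 1 of 6 higher (PRAC1) and 1 lower, with a median of -0.06, a mean of 0.29 and a downward fry direction (adjusted p = 0.820).

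Proliferation genes turned with the cluster. In ulcerative colitis their median was -0.03 with 1 of 17 higher (fry adjusted p = 0.98), and with the cluster it was 0.44 with 5 higher (fry adjusted p = 0.0209), among them BUB1, a mitotic checkpoint kinase, at 0.79 and RRM2, a subunit of ribonucleotide reductase, at 1.31. Camera with an estimated correlation called no list in ulcerative colitis with the cluster. In the Crohn's disease groups the medians turned from -0.14 to 0.18 and from -0.28 to 0.33, and no member passed with the cluster. Crypt base and stem cell genes had 1 higher and 1 lower of 10 with and without the cluster in ulcerative colitis (median 0.002 and mean -0.18). The difference between clusters C to E and clusters A and B in CH25H, an enzyme that makes a hydroxylated cholesterol, was 3.57 in healthy controls, 2.85 in colon-only Crohn's disease, 3.11 in ileocolonic Crohn's disease and 3.77 in ulcerative colitis. The same difference in OLFM4, a crypt base protein, was -4.44, -5.20, -5.33 and -5.46. The ulcerative colitis values of both genes rest on 1 array in clusters A and B.

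Other splits of the samples into groups of the same sizes tested whether chance can give as many called genes. A count reached by fewer than 5 of 100 splits, the real one included, is called rare under chance. This bound was not adjusted over the comparisons, so a share of 3 or 4 of 100 is weak evidence against chance. Labels were first exchanged freely, which leaves differences between array clusters open as the source. The count was then rare under chance for colon-only Crohn's disease against healthy controls (518 genes, 3 of 100 splits gave as many). But the highest other split called 2953. Of its 25 samples 19 followed clusters A and B against C to E while 13 followed the labels, which points to a structure of the samples. Only the real split gave as many (1 of 100) for ileocolonic Crohn's disease (3611, highest other 2253) and ulcerative colitis (8277, highest other 2936) against healthy controls. The same was so for ileocolonic Crohn's disease against ulcerative colitis (934, highest other 1). For colon-only Crohn's disease against ulcerative colitis only the real split gave as many too (120, highest other 4), but in an earlier draw 3 of 100 gave as many and the highest other split called 4113. Between the Crohn's disease groups the count of 0 genes is reached by any split (100 of 100, highest other 0) and decides nothing, and 20 of 100 splits had as many genes at an unadjusted p under 0.05 as the real 1147, so chance cannot be excluded. With labels exchanged within clusters the same holds for colon-only and ileocolonic Crohn's disease against healthy controls, where 0 genes were called with the cluster, other splits called up to 1906 and 523, and 16 and 11 of 100 splits had as many genes at an unadjusted p under 0.05. With the same exchange, the count was rare under chance for ulcerative colitis against healthy controls only in this draw (3062, 3 of 100, highest other 5005, a split that kept 19 of 21 labels). In the earlier draw 5 of 100 gave as many, so it was not rare there. Within clusters 4 of 100 splits gave as many as the 8 genes of colon-only Crohn's disease against ulcerative colitis. The highest other split there called 3402 and kept 12 of 24 labels, which points to a structure of the samples, so chance is not excluded. For ileocolonic Crohn's disease against ulcerative colitis 2 of 100 gave as many as the 622 genes (highest other 738, with 24 of 28 labels kept). The earlier draw could repeat a split (75 of its 100 were distinct for ulcerative colitis against healthy controls within clusters) and was replaced after its result was seen. It also gave 2 of 100 and a highest other of 1376 for colon-only Crohn's disease against ulcerative colitis within clusters, 7003 for ulcerative colitis against healthy controls and 94 between the Crohn's disease groups, so both the shares and the highest counts vary with the draw.

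For lists called by camera at the preset correlation, labels were first exchanged freely. The list count was then rare under chance, by the same unadjusted bound, in 3 comparisons with healthy controls. These were colon-only Crohn's disease (29 lists, 1 of 100 splits, highest other 28), ileocolonic Crohn's disease (25, 3 of 100, highest other 25) and ulcerative colitis (28, 3 of 100, highest other 28). In the last 2 another split called as many lists as the real one. Chance cannot be excluded between the Crohn's disease groups (14, 53 of 100, highest other 29), for colon-only Crohn's disease against ulcerative colitis (24, 19 of 100, highest other 28) or for ileocolonic Crohn's disease against ulcerative colitis (22, 11 of 100, highest other 27). With labels exchanged within clusters and the cluster in the model, the count was rare for ileocolonic Crohn's disease (24, 2 of 100, highest other 26) and ulcerative colitis (31, 2 of 100, highest other 32) against healthy controls. It was not rare for colon-only Crohn's disease (26, 9 of 100, highest other 30), nor in the other 3 comparisons (81, 21 and 14 of 100). Camera with an estimated correlation called 0 lists in all 6 comparisons, and fry with the cluster called 0 in both Crohn's disease groups against healthy controls. Other free splits called a median of 10 to 16 of the 39 lists, so a count of lists from this test alone says little here.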
